A study of Triticum aestivum with 18 samples.

How the data were processed

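Total RNA from single leaf samples of 6 Lr1 transgenic lines was hybridised as biotin-labelled cRNA to a 1-colour wheat 3' expression array, per the labels' protocols. Plants grew at 20 °C with a 16 h photoperiod, were sprayed with spores in mineral oil and then kept overnight at 100% humidity, per the labels. The 18 arrays fall into 3 times (0, 6 and 24 h) of 6 arrays, and the line of each array was taken from its label. The p-values of the main fit rest on the spread among the 6 arrays of a time, with 1 leaf sample per line and time. Line, plant and array are not separated in that spread. Tests with line as a term or paired by line rest on the spread left after line and time.

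The values analysed are the authors' deposited log2 signals of 61290 probe sets. The background correction, normalization and probe summary behind them are not given in the sources used here. Array medians lay between 5.23 and 5.42 and upper quartiles between 7.16 and 7.49, so the arrays had been brought near each other but not to identical distributions. A deposited table of group means and SDs, also in log2, was recomputed from the array values to within 3.3e-09. The highest Pearson r between any pair of arrays was 0.9923, and no column of values was without a sample.

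A further deposited table holds the authors' selected probe sets, with log2 means, log2 fold changes and a p-value. Recomputing showed that the p-value is unadjusted and comes from a paired test of log2 values over the 6 lines, and that its entries are those with p at most 1e-04 and at least a 1.5-fold difference of the means of unlogged values. This rule was read from the values, since no label or header states it. The same table gives, as its other kind of value per the file headers, expect scores of the best matches in UniProt, rice and Arabidopsis, which were not used to filter. It is the only annotation used here and covers 3542 probe sets, of which 3086 have a description, 5.04% of those tested, and 2748 name a product. Wheat gene models of the reference were not used, because the table of names does not list probe sets.

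From the deposited values, 111 control probe sets were left out and the remaining 61179 were tested with no filter on signal. limma 3.58.1 in R 4.3.3 fitted the 3 times to all 18 arrays with 15 residual degrees of freedom, and empirical Bayes tests were adjusted by Benjamini-Hochberg at 0.05. All tests were two-sided. Differences among lines were tested with an F test in a limma fit with time and line as terms. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, repeated with an estimated correlation and among annotated probe sets only, for lists with at least 5 members, and adjusted over the lists of a comparison. List members were found by keywords in the annotation. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

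Genes named in the text follow a rule fixed in advance. It takes the 6 highest and 6 lowest changes per comparison with 0 h among probe sets that passed, moved the same way in 6 of 6 lines and have an annotation naming a product, plus the 2 members of each list with the smallest p, with 1 probe set per annotation. It gave 41 probe sets per comparison and 58 in all. The comparison of 24 h with 6 h uses the same probe sets.

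Arrays with the same replicate number come from the same transgenic line, per the labels, so the numbers pair the samples. The deviations of same-line arrays correlated at -0.04 to 0.50 between 0 h and 6 h, -0.23 to 0.27 between 0 h and 24 h, and -0.13 to 0.54 between 6 h and 24 h. The fit without the block was the main one, as set beforehand. With the line as a replicate block 21179, 29492 and 6528 probe sets were called at 6 h, at 24 h and between them, and the consensus correlation of a random block was 0.012.

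The scripts were tested on simulated data over 61179 probe sets. For 24 h against 0 h, 81 of 100 simulated 2-fold changes and 98 of 100 simulated 4-fold changes were recovered with 10 unchanged probe sets called, and for 6 h, where none was changed, 0 were called. For lines, 196 of 200 were recovered with 8 false calls. This simulation drew independent noise for each probe set. Unchanged groups drawn from the deviations of the real arrays gave more false calls. On average they gave 393 higher and 389 lower at 6 h, and 218 higher and 190 lower at 24 h. Alternatives covered the block, quantile normalization, median centring, the brighter 30589 probe sets by mean signal, fits of only the 2 times compared, lists with 1 probe set per annotation, trended and robust variances, array weights, stricter thresholds and leaving out each line. Added after the data were seen were mapping every array on 27 hybridization control probe sets (21 bio, 6 cre), the authors' paired test, leaving out 0 h replicate 1 or 2, annotated probe sets as background and the corrected pathogenesis-related list.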

Results

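Transcript levels were measured in leaves of 6 independent transgenic lines of bread wheat (Triticum aestivum) that carry Lr1, a gene for resistance to leaf rust. The plants were sampled at 0 h, before inoculation, and at 6 h and 24 h after leaves were sprayed with spores of an avirulent isolate of the leaf rust fungus, Puccinia triticina, in mineral oil. Each line gave 1 array per time, so each time has 6 arrays and the series has 18. The series description speaks of 3 biological replicates, which the labels do not show, so n = 6 counts lines here. The lines are numbered as replicates 1 to 6. Values are log2 signals of 61179 probe sets on a wheat 3' expression array, between 3.06 and 15.51, and the number of arrays limits the precision. In a principal component analysis the 0 h arrays lay apart from all later arrays on the axis that held 63.7% of the variance, and the 6 h arrays lay apart from the 24 h arrays on the axis that held 11.2%. Of the 0 h arrays, replicate 2 lay nearest to the later times, at -91.5 against -121.5 to -183.8 for the others. Changes below are log2 differences between times with the standard error (SE) of the limma fit, from 6 arrays per time, and a named gene is the product that the authors' deposited annotation gives for a probe set.

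**Figure D1:**
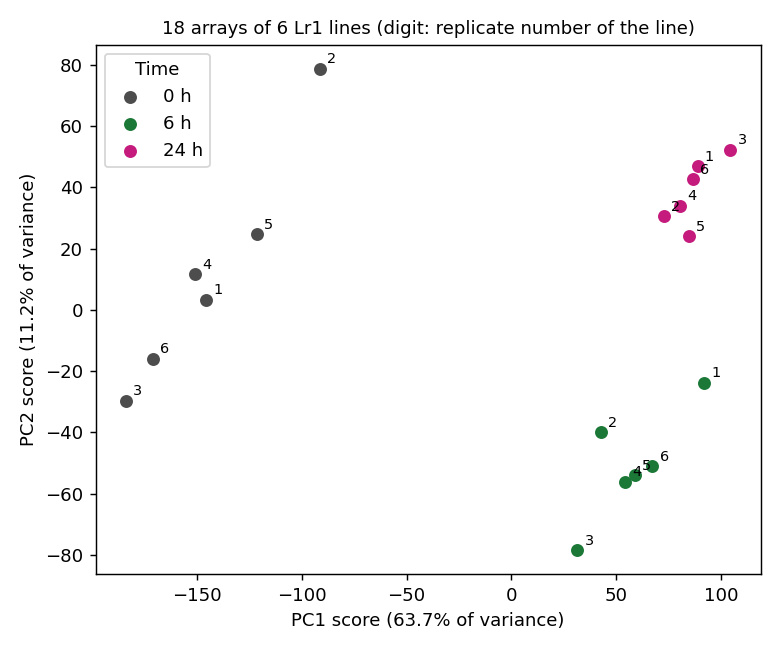
Scores of the 18 arrays on the leading pair of principal components (horizontal axis PC1, 63.7% of variance; vertical axis PC2, 11.2%), coloured by time, with the replicate number of the line beside each point. The 0 h arrays have PC1 scores from -183.8 to -91.5, and all 6 h and 24 h arrays have scores of 31.4 or higher.

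The comparison of 6 h with 0 h asks which transcripts changed early after inoculation. All arrays come from lines that carry Lr1, so the part of Lr1 in these changes was not tested. Among the annotated probe sets with the greatest rises were an inhibitor of microbial enzymes, a peroxidase and a cell wall enzyme. Xylanase inhibitor TAXI-IV, of a family that inhibits microbial xylanases, rose by 8.09 ± 0.48, from 4.65 ± 0.65 at 0 h to 12.74 ± 1.13 at 6 h (SD, n = 6). Peroxidase 6 rose by 7.94 ± 0.43, and a glycosyl hydrolase of family 16 matched to xyloglucan endotransglycosylases, enzymes that cut and rejoin wall xyloglucan, by 7.38 ± 0.47. Among the greatest falls, the early light-inducible protein HV90 of chloroplasts went down from 11.61 ± 0.68 to 3.71 ± 0.19 (SD, n = 6).

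Among the further rises, Wali3, matched to Bowman-Birk trypsin inhibitors, gained 6.82 ± 0.54. A probe set annotated as a leucine zipper protein gained 6.89 ± 0.35, and one annotated only as actin binding gained 6.48 ± 0.28. The early light-inducible protein fell by 7.90 ± 0.23. An L-asparaginase, an enzyme that releases ammonia from asparagine, fell by 7.02 ± 0.20, and chalcone synthase, the entry enzyme of flavonoid synthesis, fell by 6.86 ± 0.39. A putative heparan-alpha-glucosaminide N-acetyltransferase fell by 6.41 ± 0.13. An inhibitor of invertase or pectin methylesterase fell by 6.13 ± 0.26, and CBL-interacting protein kinase 5, of a family activated by calcium sensors, fell by 5.95 ± 0.15. By the rule that chose them, each of these 12 moved the same way in 6 of 6 lines. Their limma adjusted p ran from 5.9e-16 to 1e-08. In 9 of the 12 the lower mean was no higher than the highest of 23 control probe sets without a wheat target (means up to 5.36 at 0 h and 5.03 at 6 h). Background limits those differences, so they are lower bounds and their order is open. Other named probe sets at that level are marked as lower bounds below.

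The gene lists were fixed before the data were examined, but their members come from the authors' deposited annotation, which covers 3542 probe sets that the study selected on these same samples. Neither counts of members nor the camera p against all probe sets are therefore independent evidence of a list's direction, and the adjusted p among annotated probe sets is given as well. Of 82 probe sets in the list of pathogenesis-related and antimicrobial proteins, 48 rose, 23 fell and 11 did not pass (75 passed adjusted over the list alone). This list's camera test was up, with adjusted p = 4.2e-06, adjusted p = 0.092 with an estimated correlation and adjusted p = 0.039 among annotated probe sets. With arrays mapped on their hybridization controls the mean change of the list was 1.81 instead of 1.14, but it no longer passed against all probe sets (adjusted p = 0.35), whose median change was then 0.83. Methionine enzymes had entered that list because their name contains the word thionin. Of the 63 members left without them, 44 rose, 8 fell and 11 did not pass, with adjusted p = 1.7e-13, adjusted p = 0.028 with an estimated correlation and adjusted p = 0.0015 among annotated probe sets. Chitinase 2, an enzyme that cuts the chitin of fungal walls, rose by 5.03 ± 0.28 (a lower bound). S-adenosylmethionine synthetase 1, one of the misplaced enzymes, makes the methyl donor of the cell and fell by 3.23 ± 0.20.

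Peroxidases, oxidases and detoxification enzymes had 48 members, of which 32 rose, 11 fell and 5 did not pass (46 passed adjusted over the list alone). The camera adjusted p was 5.8e-08, with adjusted p = 0.032 with an estimated correlation. A peroxidase precursor rose by 6.11 ± 0.25 and a glutathione S-transferase by 4.42 ± 0.18 (a lower bound). All 5 WRKY transcription factors of the list rose, with adjusted p = 2e-06 and adjusted p = 0.032 with an estimated correlation, and all 5 passed adjusted over the list alone. WRKY4 rose by 5.16 ± 0.28 and WRKY14 by 3.44 ± 0.27.

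Receptor-like kinases and NBS-LRR homologues, the class of proteins to which many resistance genes belong, had 74 members, of which 46 rose, 21 fell and 7 did not pass (70 passed adjusted over the list alone), with adjusted p = 7.9e-08 and adjusted p = 0.032 with an estimated correlation. Its members with the smallest p were a leucine-rich repeat and extensin family protein, which rose by 4.50 ± 0.11, and a putative regulatory subunit with leucine-rich repeats, which rose by 2.93 ± 0.13. Neither annotation names a kinase or a nucleotide-binding domain. In the list of jasmonate, ethylene and oxylipin genes, 19 of 28 rose and 9 fell (28 passed adjusted over the list alone), with adjusted p = 1.2e-06 and adjusted p = 0.033 with an estimated correlation. Its leading members are transcription factors and not enzymes of hormone synthesis. Ethylene-responsive element binding protein 2 rose by 5.85 ± 0.20 (a lower bound), and the pathogen-inducible factor ERF3 by 5.25 ± 0.16. Of 22 members of the list of cell wall loosening enzymes, 16 rose, 5 fell and 1 did not pass (21 passed adjusted over the list alone), with adjusted p = 2.9e-06 and adjusted p = 0.043 with an estimated correlation. A second probe set of the xyloglucan enzyme rose by 7.37 ± 0.39, while the inhibitor of invertase or pectin methylesterase named above belongs to this list without loosening walls. Among annotated probe sets the adjusted p was 0.028 for the peroxidase and the receptor-like kinase lists and 0.039 for the WRKY, jasmonate and cell wall lists. Mapping on the hybridization controls ended the calls of the peroxidase (adjusted p = 0.26), receptor-like kinase (0.92), jasmonate (0.82) and cell wall (0.28) lists against all probe sets, although their mean changes rose, while the WRKY list still passed (0.0069).

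Photosynthesis probe sets fell, with 4 of 27 higher, 19 lower and 4 not passing (23 passed adjusted over the list alone), adjusted p = 1.5e-06 and adjusted p = 0.032 with an estimated correlation. Set against annotated probe sets only, that adjusted p was 0.058. The photosystem II protein PSB28 fell by 4.81 ± 0.22, and oxygen-evolving enhancer protein 3-2 fell by 5.22 ± 0.36. Histones, the proteins that package DNA, had 5 of 6 members lower and 1 higher (6 passed adjusted over the list alone), with adjusted p = 0.00023 and adjusted p = 0.032 with an estimated correlation, and 0.15 as the adjusted p among annotated probe sets. Histone H2B.3 fell by 3.48 ± 0.19 and histone H4 fell by 3.11 ± 0.20. In the ribosomal list 5 of 18 rose, 11 fell and 2 did not pass (16 passed adjusted over the list alone), with adjusted p = 0.017 and adjusted p = 0.16 with an estimated correlation. Its leading members, an RNase P-associated protein, which fell by 2.36 ± 0.13, and a ClpS adaptor of the Clp protease, which fell by 1.28 ± 0.09, are not structural ribosomal proteins by their annotation.

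Other lists moved both ways at 6 h. Among 23 phenylpropanoid and lignin enzymes 9 rose, 12 fell and 2 did not pass (21 passed adjusted over the list alone; camera adjusted p = 0.21). Caffeoyl-CoA O-methyltransferase, of lignin monomer synthesis, rose by 5.62 ± 0.18, while cinnamate 4-hydroxylase, of the shared upstream pathway, fell by 4.93 ± 0.22 (a lower bound). Of 58 calcium signalling probe sets 28 rose, 27 fell and 3 did not pass (55 passed adjusted over the list alone), with median 0.33, mean -0.14 and adjusted p = 0.65. Another probe set of CBL-interacting protein kinase 5 fell by 4.78 ± 0.12, and kinase 11 of that family fell by 3.03 ± 0.11 (both lower bounds). Clock and light timing genes divided into 11 higher and 11 lower (22 passed adjusted over the list alone), with median -0.05, mean 0.43 and adjusted p = 0.87. A CCT motif protein matched to pseudo-response regulators of the clock rose by 4.75 ± 0.21, and CONSTANS-like protein CO9 fell by 5.24 ± 0.19 (a lower bound). Cyclin-A1-1, of the cell division cycle, which rose by 1.77, and the chloroplast import component Toc159, which fell by 2.01, are members by their abbreviations and not by a role in timing.

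Heat shock proteins and chaperones had 13 of 50 members higher, 23 lower and 14 not passing (39 passed adjusted over the list alone; adjusted p = 0.073). A DnaJ heat shock protein rose by 4.44 ± 0.26 and a heat shock factor fell by 3.23 ± 0.18. For dehydrins, late embryogenesis abundant (LEA) and cold-regulated proteins, 13 of 39 rose, 20 fell and 6 did not pass (36 passed adjusted over the list alone), with adjusted p = 0.072, and 0.04 with the lines as a block. An LEA group 1 protein fell by 3.14 ± 0.16 and an early-responsive to dehydration protein fell by 2.84 ± 0.17. Without replicates 1, 3 or 6 the heat shock list passed (adjusted p = 0.041, 0.019 and 0.04), and without replicates 3 or 6 so did the dehydrin list (adjusted p = 0.044 and 0.031). With 1 probe set per annotation the dehydrin list had a mean of -0.10 instead of -0.58 and adjusted p = 0.97. Cuticle and wax genes, included as markers of the epidermis, had 4 of 7 members higher and 3 lower (7 passed adjusted over the list alone; adjusted p = 0.51). A lipid-transfer family protein rose by 5.14 ± 0.39 (a lower bound) and a non-specific lipid-transfer protein fell by 2.47 ± 0.11. The list of fungal transcripts had 0 members. The list of seed storage proteins, a tissue that was not sampled, had 2 members with 1 annotation, both higher, with a median of 2.95 at 6 h.

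At 6 h, 10515 probe sets were higher and 10754 lower, 21269 in all or 34.8% of those tested, with limma adjusted p under 0.05, and 15924 of them moved the same way in 6 of 6 lines. At least 2-fold changes numbered 4625 higher and 3466 lower. The hybridization controls bioB, bioC and bioD, RNA added equally to every array, averaged 10.04 ± 0.18 at 0 h and 9.61 ± 0.08 at 6 h, while the brighter cre controls averaged 13.81 ± 0.07 and 13.81 ± 0.06 (SD, n = 6). With arrays mapped on the 21 bio and 6 cre probe sets together, the median change of all probe sets was 0.83 instead of -0.06. With that mapping 50938 were called higher and 3419 lower. The directions given here are therefore relative to the deposited normalization. The dimmest of these controls averaged 7.91 at 0 h and 7.41 at 6 h, while array medians lay between 5.23 and 5.42. For most probe sets the mapping therefore extrapolates below its controls, which limits what this shift can show. No uninoculated or oil-treated arrays of the later times were analysed here, so oil, humidity and the fungus act together in each comparison with 0 h, joined by time of day at 6 h.

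**Figure D2:**
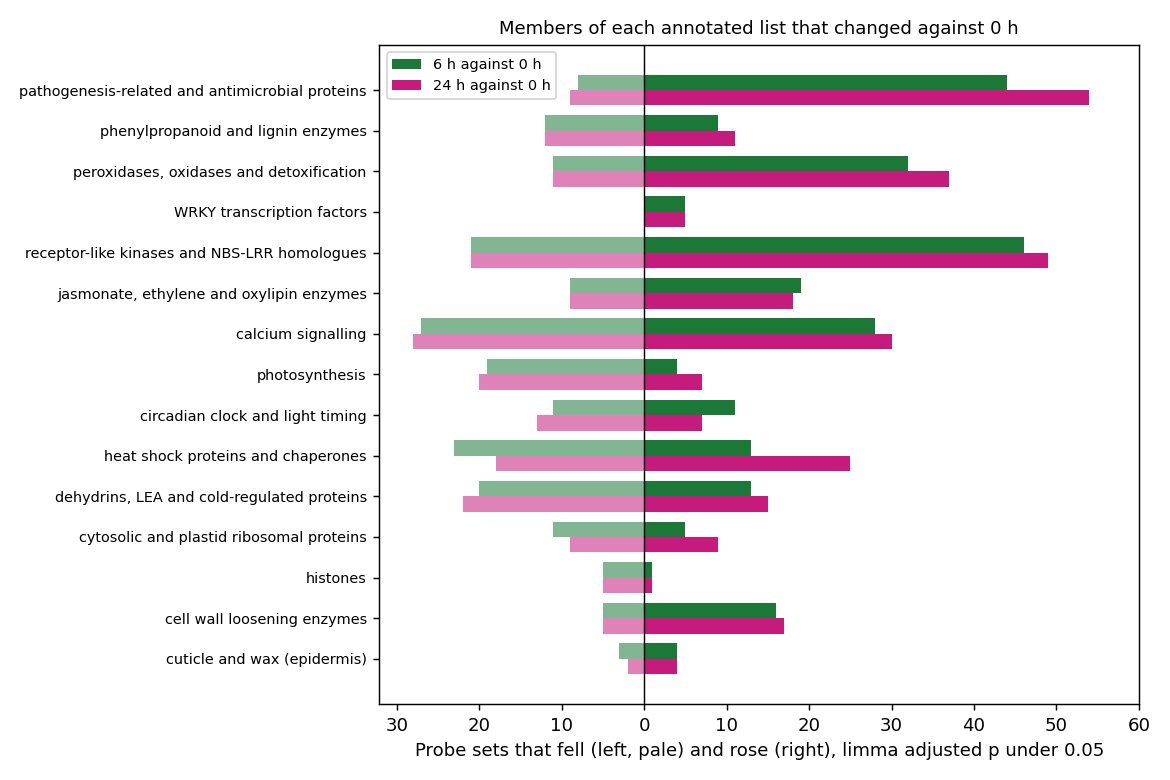
Number of probe sets in each annotated list that rose (to the right) or fell (to the left, pale) at 6 h and at 24 h against 0 h, with limma adjusted p under 0.05; the pathogenesis-related bar leaves out the methionine enzymes. Its risers go from 44 at 6 h to 54 at 24 h, and photosynthesis has 19 and 20 members to the left.

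The comparison of 24 h with 0 h asks what the leaves had changed a day after inoculation. Among the greatest annotated rises, glucan endo-1,3-beta-glucosidase GII, which cuts the beta-glucan of fungal walls, rose by 8.48 ± 0.23, from 3.76 ± 0.12 at 0 h to 12.24 ± 0.32 at 24 h (SD, n = 6). The xyloglucan enzyme rose by 8.70 ± 0.47 and xylanase inhibitor TAXI-IV by 8.38 ± 0.48. MPI, matched to protease inhibitors, rose by 8.33 ± 0.78. The early light-inducible protein HV90, asparaginase and chalcone synthase were again among the greatest falls, at -7.96 ± 0.23, -7.07 ± 0.20 and -6.96 ± 0.39.

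An iron/ascorbate-dependent oxidoreductase rose by 8.27 ± 0.31 and isocitrate lyase, of the glyoxylate cycle, by 7.89 ± 0.37. Oxygen-evolving enhancer protein 3-2 fell by 6.71 ± 0.36, and a steroid 5alpha-reductase-like protein fell by 6.50 ± 0.31. A probe set whose best match is a worm jaw protein, and whose rice match is a glycine-rich cell wall protein, fell by 6.24 ± 0.33. By the rule that chose them, each of these 12 probe sets moved the same way in 6 of 6 lines. Their limma adjusted p ran from 1.2e-14 to 9.1e-08. In 10 of the 12, among them the glucosidase at 0 h and HV90, asparaginase and chalcone synthase at 24 h, the lower mean was no higher than the highest control probe set without a wheat target (4.92 at 24 h). These differences too are lower bounds, and their order is open.

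List counts and camera p at 24 h carry the same limit as at 6 h, since the study chose the annotated probe sets on these samples. Of the 82 pathogenesis-related probe sets 58 rose, 23 fell and 1 did not pass (81 passed adjusted over the list alone), with adjusted p = 2.5e-13 and adjusted p = 0.026 with an estimated correlation. Without the methionine enzymes 54 of 63 rose and 9 fell, with a median of 4.03, adjusted p = 4.9e-27, adjusted p = 0.0085 with an estimated correlation and adjusted p = 1.3e-07 among annotated probe sets. An endochitinase rose by 6.26 ± 0.22 (a lower bound). For peroxidases, oxidases and detoxification 37 of 48 rose and 11 fell (48 passed adjusted over the list alone), with adjusted p = 2.5e-13 and adjusted p = 0.016 with an estimated correlation. Oxalate oxidase GF-2.8, a germin that makes hydrogen peroxide, rose by 7.56 ± 0.26 (a lower bound), and glutathione S-transferase GST 37 fell by 3.52 ± 0.13. The 5 WRKY factors stayed above 0 h (5 passed adjusted over the list alone), with adjusted p = 1.9e-05, adjusted p = 0.04 with an estimated correlation and adjusted p = 0.055 among annotated probe sets. WRKY4 was up by 4.66 ± 0.28 and WRKY14 by 3.12 ± 0.27.

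Receptor-like kinases and NBS-LRR homologues had 49 of 74 members higher, 21 lower and 4 not passing (70 passed adjusted over the list alone), with adjusted p = 2.4e-08 and adjusted p = 0.026 with an estimated correlation. The leucine-rich repeat and extensin family protein was up by 4.44 ± 0.11, and the regulatory subunit by 2.72 ± 0.13. For jasmonate, ethylene and oxylipin genes 18 of 28 rose, 9 fell and 1 did not pass (27 passed adjusted over the list alone). That list's adjusted p was 5.9e-05 upward, with adjusted p = 0.07 with an estimated correlation, and adjusted p = 0.07 among annotated probe sets. With arrays mapped on the hybridization controls its mean change was 1.74 instead of 1.24, but it did not pass against all probe sets (adjusted p = 0.63). Ethylene-responsive element binding protein 2 was up by 5.27 ± 0.20 (a lower bound) and ERF3 by 3.89 ± 0.16. Cell wall loosening enzymes had 17 of 22 members higher and 5 lower (22 passed adjusted over the list alone), with adjusted p = 6.5e-07 and adjusted p = 0.034 with an estimated correlation. A polygalacturonase-inhibiting protein, which blocks a microbial pectinase and does not loosen walls, rose by 4.65 ± 0.21 (a lower bound), and the inhibitor of invertase or pectin methylesterase fell by 5.99 ± 0.26. Among annotated probe sets the adjusted p was 0.00056 for peroxidases, 0.013 for receptor-like kinases and 0.027 for the cell wall list. Mapping on the hybridization controls ended the calls of the pathogenesis-related list of 82 (adjusted p = 0.15), the receptor-like kinase list (0.88) and the cell wall list (0.21) against all probe sets, although their mean changes rose, while peroxidases (0.012) and WRKY factors (0.016) still passed.

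Photosynthesis probe sets were lower in 20 of 27 cases and higher in 7 (27 passed adjusted over the list alone), with adjusted p = 6.5e-06, adjusted p = 0.034 with an estimated correlation and adjusted p = 0.052 among annotated probe sets. PSB28 fell by 5.27 ± 0.22, and a methyltransferase of the Rubisco small subunit fell by 3.75 ± 0.17. Of 6 histones 5 fell and 1 rose (6 passed adjusted over the list alone), with adjusted p = 0.0018, adjusted p = 0.026 with an estimated correlation and adjusted p = 0.17 among annotated probe sets. Histone H2B.3 fell by 3.72 ± 0.19 and histone H4 fell by 2.97 ± 0.20.

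In the remaining lists the camera test did not pass at 24 h. Phenylpropanoid and lignin enzymes had 11 of 23 members higher and 12 lower (23 passed adjusted over the list alone; adjusted p = 0.90). Caffeoyl-CoA O-methyltransferase was up by 6.14 ± 0.18, and a dehydratase matched to cinnamyl-alcohol dehydrogenase fell by 2.74 ± 0.12. Calcium signalling had 30 of 58 higher and 28 lower (58 passed adjusted over the list alone), with median 0.46, mean -0.21 and adjusted p = 0.90. The second probe set of CBL-interacting protein kinase 5 fell by 4.60 ± 0.12, and kinase 11 fell by 3.08 ± 0.11 (both lower bounds). The clock list had 7 of 22 higher, 13 lower and 2 not passing (21 passed adjusted over the list alone; adjusted p = 0.09, and 0.037 without replicate 1). CONSTANS-like protein CO9 fell by 3.58 ± 0.19 and a glycine-rich RNA-binding protein rose by 2.25 ± 0.12. Heat shock proteins and chaperones had 25 of 50 higher, 18 lower and 7 not passing (43 passed adjusted over the list alone; adjusted p = 0.39). The DnaJ protein was up by 4.48 ± 0.26, while a copper chaperone, which carries metal and does not fold proteins, fell by 4.63 ± 0.28 (a lower bound).

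Dehydrins, LEA and cold-regulated proteins had 15 of 39 higher, 22 lower and 2 not passing (37 passed adjusted over the list alone; adjusted p = 0.20). An LEA protein matched to a senescence-associated gene fell by 6.18 ± 0.30, and DEHYDRATION-INDUCED 19 rose by 1.72 ± 0.09. Ribosomal probe sets divided into 9 higher and 9 lower (18 passed adjusted over the list alone; adjusted p = 0.55). The RNase P-associated protein fell by 2.19 ± 0.13 and the ClpS adaptor fell by 1.95 ± 0.09. The 7 cuticle and wax probe sets gave 4 higher, 2 lower and 1 not passing (6 passed adjusted over the list alone; adjusted p = 0.54). The non-specific lipid-transfer protein fell by 2.26 ± 0.11, and a 3-ketoacyl-CoA synthase, of very-long-chain fatty acid synthesis, fell by 1.86 ± 0.19. Both seed storage probe sets were higher, with a median of 2.70.

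At 24 h, 13639 probe sets were higher and 16402 lower with limma adjusted p under 0.05, 30041 in all or 49.1% of those tested, and 20727 of them moved the same way in 6 of 6 lines. At least 2-fold changes numbered 6229 higher and 3704 lower. In the dimmest of 4 equal groups of probe sets by mean signal, 394 were higher and 2460 lower, while 7465 were higher and 3906 lower in the brightest. The bio hybridization controls averaged 9.65 ± 0.12 and the cre controls 13.96 ± 0.09 at 24 h (SD, n = 6), and 23 control probe sets without a wheat target fell by a median of 0.19. With arrays mapped on the hybridization controls, 50755 probe sets were called higher and 3621 lower with a median change of 0.89 instead of -0.08.

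**Figure D3:**
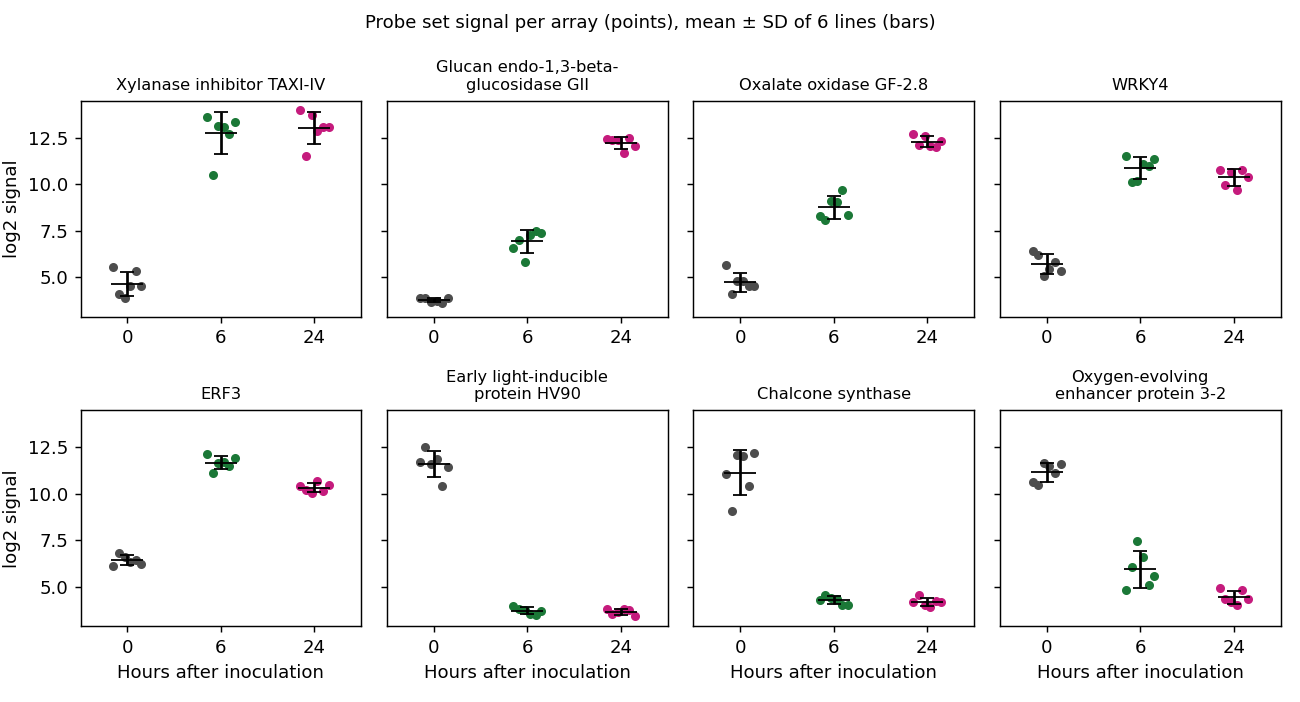
Log2 signal of 8 probe sets (vertical axis) at 0, 6 and 24 h after inoculation (horizontal axis), each point an array, with mean and SD of 6 lines. Glucan endo-1,3-beta-glucosidase GII and oxalate oxidase GF-2.8 climb from 6 h to 24 h, ERF3 declines from 11.68 to 10.33, and the early light-inducible protein lies at 3.71 and 3.65 at the later times.

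The comparison of 24 h with 6 h asks which transcripts kept changing between the sampled times after inoculation. Most pathogenesis-related probe sets were higher at 24 h than at 6 h, while some named probe sets that had risen by 6 h declined. Glucan endo-1,3-beta-glucosidase GII rose by a further 5.32 (adjusted p = 1.5e-10), the endochitinase by 3.73 (adjusted p = 1e-08) and oxalate oxidase GF-2.8 by 3.53 (adjusted p = 1.7e-07). ERF3 fell by 1.36 (adjusted p = 2.8e-05), the leucine zipper protein fell by 1.67 (adjusted p = 0.0045) and the CCT motif protein matched to clock regulators fell by 2.00 (adjusted p = 7.1e-06). No WRKY factor of the 5 passed between 6 h and 24 h (camera adjusted p = 0.44), and neither did ethylene-responsive element binding protein 2 (-0.58, adjusted p = 0.086).

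Without the methionine enzymes, 48 of 63 pathogenesis-related probe sets rose between 6 h and 24 h, 2 fell and 13 did not pass (53 passed adjusted over the list alone), with adjusted p = 3.1e-44 and adjusted p = 0.0018 with an estimated correlation. Peroxidases, oxidases and detoxification had 21 of 48 higher, 5 lower and 22 not passing (33 passed adjusted over the list alone), with adjusted p = 5.9e-10 and adjusted p = 0.025 with an estimated correlation. Phenylpropanoid and lignin enzymes had 5 of 23 higher, 0 lower and 18 not passing (11 passed adjusted over the list alone), with adjusted p = 9e-05, adjusted p = 0.03 with an estimated correlation and adjusted p = 0.072 among annotated probe sets. In the heat shock list 25 of 50 rose and 8 fell (36 passed adjusted over the list alone), with adjusted p = 8e-07 and adjusted p = 0.10 with an estimated correlation. The photosynthesis list had 11 of 27 members lower and 4 higher (21 passed adjusted over the list alone), with adjusted p = 0.00096 and adjusted p = 0.15 with an estimated correlation. Receptor-like kinases and NBS-LRR homologues had 15 of 74 higher, 11 lower and 48 not passing (34 passed adjusted over the list alone), with adjusted p = 0.11, and 0.048 with the lines as a block. Isocitrate lyase rose by 1.48 (adjusted p = 0.015), the Rubisco methyltransferase fell by 1.68 (adjusted p = 6.2e-06) and oxygen-evolving enhancer protein 3-2 fell by 1.49 (a lower bound, adjusted p = 0.012).

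Between 6 h and 24 h, 3570 probe sets were higher and 1996 lower with limma adjusted p under 0.05, 5566 in all or 9.1% of those tested. The count was 3358, 3390 and 3032 without replicates 3, 4 and 6, and 12323 with array weights.

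Most genes called at both times moved the same way. Higher at both times were 9131 probe sets and lower at both were 9184, against 2340 and 2880 for independent lists, and 93 moved in opposite directions. The comparisons share their 0 h arrays, so independent lists are not a full baseline. Across probe sets, which are not independent, the changes at 6 h and 24 h had Pearson r = 0.90 and a covariance of 0.726. Unchanged groups simulated against the same 0 h arrays gave r = 0.566 and a covariance of 0.0219, a difference of 0.704 from the observed covariance. With separate 0 h arrays for each time, in 20 divisions, r was 0.765 to 0.89 and the covariance 0.655 to 0.724. In those divisions, with fewer 0 h arrays per comparison, 6099 to 7810 probe sets were higher at both times (median 6932), 4966 to 6481 lower at both (median 5818) and 22 to 372 opposite. Risers at 24 h that had not passed at 6 h and also stood above 6 h by the test of that difference numbered 1762, and 454 fell at 24 h in the same sense. Higher at 6 h without passing at 24 h, with a decline after 6 h by that test, were 372, and the matching class lower at 6 h held 384.

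The 6 lines were compared to find probe sets whose signal differed among the transgenic lines. A probe set whose identifier begins with RPTR, RPTR-Ta-K01193-1_at, was low in the line of replicate 4, at 6.27 ± 0.54 (SD over 3 times), against means of 11.06 to 12.83 in the other lines (limma adjusted p = 3.1e-06). What that probe set detects is not given in the sources used here, so its signal is not read as that of a wheat gene. In the line of replicate 5 another probe set was at 5.23 ± 0.22 against 12.23 to 12.69 elsewhere (adjusted p = 8.3e-07). In the line of replicate 6 a further probe set was at 10.95 ± 0.38, while the other lines lay between 3.83 and 3.91 (adjusted p = 1.7e-10). The files do not pair these 3 probe sets with gene names, and they were picked after their values were seen. In all, 655 probe sets differed among lines in a fit with time as a term, and 260 to 497 did so when 1 line was left out (268, 340, 260 and 408 without replicates 2, 4, 5 and 6). Probe sets that deviated by over 2 log2 units in all 3 arrays of a line numbered 25 in the line of replicate 5 (21 lower), 18 in that of replicate 6 (10 higher) and 11 in that of replicate 4 (8 lower), and 3, 4 and 3 in those of replicates 1, 2 and 3. Each line has 1 array per time, so line, plant and array handling are separated only by the 3 times.

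**Figure D4:**
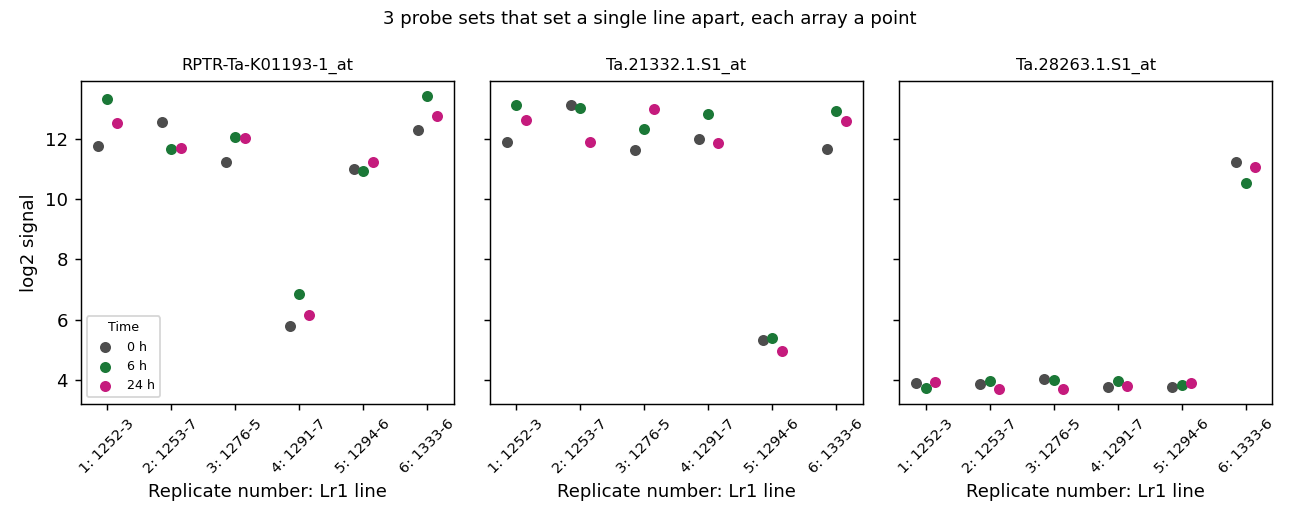
Log2 signal (vertical axis) of 3 probe sets in the 6 Lr1 lines (horizontal axis), each point 1 array coloured by time. The left probe set, RPTR-Ta-K01193-1_at, is low in the line of replicate 4, the middle one is low in that of replicate 5, and the right one averages 10.95 in that of replicate 6 and 3.83 to 3.91 in the others.

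The authors' deposited table lists 2252 probe sets for 6 h against 0 h, 2441 for 24 h against 0 h and 315 for 24 h against 6 h. Of those, 2250, 2441 and 303 passed limma adjusted p under 0.05, and all had the same sign. The limma fit called a further 19019, 27600 and 5263 probe sets outside the authors' deposited table for that comparison. Of the 3542 probe sets in the authors' deposited table, 1602 rose and 1784 fell at 6 h by limma, and 1691 rose and 1768 fell at 24 h.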

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

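Chosen only after the result was seen were the tests of calls left by quantile normalization, of the ratio of the 24 h to the 6 h changes, of the controls without a wheat target and of single arrays or labels, and mapping on hybridization controls was added as a setting after the data were seen.

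The changes at 6 h and 24 h against 0 h ran together. Quantile normalization, which removes any response that only rises with signal, left 27660 probe sets called at 24 h against 30041, which argues against such a response as the whole cause; the mapping on hybridization controls gave 54376 but made the median change of all probe sets 0.89, so that test cannot tell. Time of day differs between 0 h and 6 h but not between 0 h and 24 h, and the median ratio of the 24 h to the 6 h change was at least 0.612 in the 20 divisions of the 0 h arrays (highest 1.02), which argues against time of day for the shared changes. Of the 22 clock list members called at 6 h, 4 kept under 0.5 of that change at 24 h, and 4 to 7 did with separate 0 h arrays for each change in 20 divisions, as they did among the 20 left without Cyclin-A1-1 and Toc159. The cut at 0.5 passes over members that moved back in part, such as the CCT motif protein (4.75 at 6 h, 2.75 at 24 h) and CONSTANS-like CO9 (-5.24 and -3.58). By the test of 24 h against 6 h, 12 of the 22 did not pass. These include Cyclin-A1-1, Toc159 and every probe set matched to ZEITLUPE. Every probe set matched to a pseudo-response regulator moved back toward or past its 0 h level (limma adjusted p = 2.2e-07 to 0.015). The members come only from probe sets that the study selected on these same samples. The 22 members carry 16 annotation texts, so they are not independent. Time of day therefore does not account for the whole change of most members. Its part in these changes stays open, most of all for the pseudo-response regulators. The 4 that returned may follow time of day. They are 3 probe sets for the clock regulator PRR1 and a CCT/B-box zinc finger protein (3.22 at 6 h, -0.48 at 24 h). Another CCT/B-box probe set outside the list (2.85 and -0.41), picked after its values were seen, may also follow time of day. Inoculation with an avirulent isolate, oil and humidity remain open, since no array separates them. The controls of the 0 h arrays differed from the later ones. Their bio controls averaged 10.04 against 9.61 and 9.65 later, and their slopes on the hybridization controls were 0.911 to 0.98 against 1.007 to 1.063. The median shifts of these controls at 24 h (-0.43) and of the controls without a wheat target (-0.19) are far smaller than the changes of TAXI-IV or HV90. The sources used here give no batches. Mapping on the hybridization controls moved the median change of all probe sets at 24 h from -0.08 to 0.89, more than those shifts, though by extrapolation. The shifts therefore set no limit of their own on the changes for which the processing of the 0 h arrays may matter. The named changes, TAXI-IV and HV90 among them, kept 67% to 118% of their log2 size under this mapping, quantile normalization and the other settings tried for them. They were picked by their size or p, so this range covers no other probe sets.

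Dim probe sets fell at 24 h more often than they rose, with 6.24 falls per rise in the dimmest of 4 equal groups by signal. After quantile normalization there were 975 falls and 802 rises, 1.22 falls per rise, but this normalization gives all arrays equal distributions and so largely sets that balance. Whether a different spread of values on the 0 h arrays is the cause therefore stays open. Control probe sets without a wheat target changed by a median of -0.19, against a median of -0.27 for the dim probe sets called lower, so a background that differs between arrays is a candidate explanation. No biological explanation was tested for it.

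A set of probe sets stood apart in single lines. In the line of replicate 6, 18 probe sets deviated by over 2 log2 units in all 3 arrays, which argues against a single array or a single wrong label. Several of the leading ones share the identifier stem Ta.7259, so they are not independent. The 655 probe sets that differed among lines compare with at most 36 in 99 other draws of line numbers within times. That is 1 of 100 with the real one, the lowest share that this test can give, which argues against chance. Transgene insertion, genetic background and growing position of the line remain open as untested explanations. The prefix RPTR may stand for reporter or marker sequences used in transformation, in which case the low signal in the line of replicate 4 may reflect the construct it carries and not a wheat gene, but the files do not say so and it was not tested.

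The splits also argue against chance for the time comparisons, with 1 of 100 drawn splits, the real one, as large in each. That is the lowest share that this test can give, and it does not separate time from array processing. Fits of only the times compared gave 18410 calls at 6 h (14794 in the highest other split), 27432 at 24 h (21044) and 7908 between 6 h and 24 h (9). The lines pair the samples, and among the 32 splits that exchange times within lines, with the lines as a block, the real ones gave 18565, 24077 and 8869 and the highest other gave 0 in each comparison.

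Single arrays far from the other 5 of their time appeared in 18 of 174 groups of named probe sets, where chance gives about 1 in 20. At 6 h, TAXI-IV was 10.51 in replicate 2 (others from 12.72), L-asparaginase 5.00 in replicate 3, CBL-interacting protein kinase 11 4.40 in replicate 3, CONSTANS-like CO9 5.35 in replicate 1, the LEA group 1 protein 5.28 in replicate 2 and the copper chaperone 5.61 in replicate 2. At 24 h, replicate 5 had peroxidase 6 at 13.31, the peroxidase precursor at 13.17, the CCT motif protein at 10.06 and the ClpS adaptor at 10.93. Also at 24 h, the LEA group 1 protein was 5.67 in replicate 2, the dehydratase matched to cinnamyl-alcohol dehydrogenase 8.89 in replicate 3 and DEHYDRATION-INDUCED 19 13.98 in replicate 4. At 0 h, replicate 5 had S-adenosylmethionine synthetase 1 at 12.87, the iron/ascorbate-dependent oxidoreductase at 5.68 and the LEA protein matched to a senescence-associated gene at 12.39, replicate 4 had caffeoyl-CoA O-methyltransferase at 5.91 and replicate 6 the endochitinase at 4.62. The poly-A spike controls averaged 8.23 in 0 h replicate 1 against 9.53 to 10.3, and the wheat control probe sets 7.16 in 6 h replicate 2 against 7.32 to 7.40.

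The changes at 6 h and 24 h differed by the limma test of 24 h against 6 h for named probe sets. Higher at 24 h than at 6 h were glucan endo-1,3-beta-glucosidase GII by 5.32, MPI by 3.90, the endochitinase by 3.73, oxalate oxidase by 3.53, the iron/ascorbate-dependent oxidoreductase by 2.37, CONSTANS-like CO9 by 1.65 (a lower bound), isocitrate lyase by 1.48, the early-responsive to dehydration protein by 1.01, the polygalacturonase-inhibiting protein by 0.78, the LEA group 1 protein by 0.62 and DEHYDRATION-INDUCED 19 by 0.44. Lower at 24 h than at 6 h were the glycine-rich wall protein match at -3.40 (limited by background at 24 h), the CCT motif protein, which fell by 2.00, the LEA protein matched to a senescence-associated gene at -1.88, the steroid 5alpha-reductase-like protein at -1.83, the Rubisco methyltransferase at -1.68, the leucine zipper protein at -1.67, oxygen-evolving enhancer protein 3-2 at -1.49 (limited likewise), the lipid-transfer family protein at -1.48, ERF3 at -1.36, GST 37 at -1.32, the ClpS adaptor at -0.67 and the glutathione S-transferase that was higher at 6 h at -0.63.

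By camera, lists also differed between the times, given as the mean difference of 24 h from 6 h. The pathogenesis-related list was 1.5 higher (1.94 without methionine enzymes), peroxidases and oxidases 0.81, phenylpropanoid enzymes 0.62, cell wall loosening 0.44, heat shock 0.41 and ribosomal 0.29. The clock list was at -0.67, photosynthesis at -0.51 and jasmonate and ethylene at -0.26. With an estimated correlation only the pathogenesis-related, peroxidase and phenylpropanoid lists still passed, and camera adjusted p was 0.19 for cell wall loosening, 0.10 for heat shock, 0.21 for ribosomal, 0.23 for clock, 0.15 for photosynthesis and 0.19 for jasmonate. Among annotated probe sets only the pathogenesis-related, peroxidase and heat shock lists passed.

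Among control probe sets, which no comparison used, some averaged outside the range of the 0 h arrays. AFFX-Ta_Sucsyn_3_at averaged 10.89 at 6 h and 10.77 at 24 h (highest 0 h array 9.97), AFFX-Ta_Sucsyn_M_at 9.84 and 9.76 (8.83), and AFFX-Ta_Sucsyn_5_at 6.18 and 5.90 (5.53). AFFX-Ta_18SrRNA_at averaged 11.73 at 6 h against a highest 0 h array of 11.46. Below the lowest 0 h array were AFFX-Ta-actin-M_at at 7.54 at both later times (8.04), AFFX-Ta-actin-M_x_at at 5.43 and 5.4 (5.99) and AFFX-Ta-actin-3_at at 4.44 and 4.24 (4.70). Other control probe sets also lay below it, such as AFFX-r2-Ec-bioB-5_at at 7.75 and 7.87 (8.31).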

How the results depend on the processing

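All 982 alternative values of the named probe sets kept their direction and their side of the threshold, at 67% to 118% of the reported log2 change. Not tried for them were the paired test, array weights, fits of only the 2 times compared and the random block. Stricter thresholds and leaving out 0 h replicate 1 or 2 were not tried for them either. The named probe sets were picked from these same data by their largest changes or smallest p. Their 982 values are therefore no independent test of the other probe sets. Of 535 alternative values of counts, lists and agreement, 456 kept direction and side, or for counts lay within 1.5 times. Mapping on hybridization controls, the authors' paired test, both 0 h replicates left out, the annotated background and the corrected list were added after the data were seen. The array number and the signal over background limit small changes of dim probe sets. Unless stated, the cause of a change was not tested.

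A 2-fold minimum left 8091, 9933 and 1889 probe sets at 6 h, at 24 h and between them, and adjusted p under 0.01 left 2809 between 6 h and 24 h, both by their construction. The paired test gave 2252, 2441 and 315 at the authors' limits, and after Benjamini-Hochberg adjustment 18764 at 24 h and 3279 between the times. Array weights gave 12323 between the times, and leaving out an array or line gave 3032 to 7146. Hybridization control mapping gave 54357, 54376 and 3019, with the medians given above. Differences among lines numbered 260 to 497 without 1 line, with fewer lines tested. The brighter 30589 probe sets had a covariance of 1.35 between the changes, against 0.726 for all probe sets. Separate 0 h arrays for each time left 5818 probe sets lower at both times, with fewer arrays.

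With the lines as a replicate block 21179, 29492 and 6528 probe sets were called, and no list changed its call against 0 h except the dehydrin list at 6 h (adjusted p = 0.04). Between 6 h and 24 h the block changed only the call of the receptor-like kinase list (adjusted p = 0.048). Values that follow are camera adjusted p. With an estimated correlation the pathogenesis-related (0.092) and ribosomal (0.16) lists at 6 h and the jasmonate list at 24 h (0.07) no longer passed. Among annotated probe sets the ribosomal (0.46), histone (0.15) and photosynthesis (0.058) lists at 6 h, and the histone (0.17), jasmonate (0.07), photosynthesis (0.052) and WRKY (0.055) lists at 24 h no longer passed.

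Quantile normalization made the dehydrin (0.015) and heat shock (0.0053) lists at 6 h and the clock list at 24 h (0.014) pass downward, and turned calcium signalling at 6 h (0.95) and 24 h (0.65) and the clock list at 6 h (0.74) downward. The brighter 30589 probe sets did so for dehydrins (0.041) and heat shock (0.014) at 6 h and the clock at 24 h (0.032), and turned calcium at 6 h (0.92) and 24 h (0.61), the clock at 6 h (0.76) and heat shock at 24 h (0.80) downward. Leaving out a line or a 0 h array gave ranges of 0.60 to 0.99 for the clock list at 6 h and 0.037 to 0.23 at 24 h, 0.031 to 0.13 for dehydrins and 0.019 to 0.23 for heat shock at 6 h, and 0.69 to 0.97 for calcium and 0.62 to 0.97 for phenylpropanoids at 24 h, and the direction turned for the clock list at 6 h without replicate 1 (0.84), replicate 3 (0.93) or 0 h replicate 1 (0.99), for calcium without replicate 3 (0.97) and for phenylpropanoids without replicate 4 (0.87).

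Mapping on hybridization controls raised the mean change of all 30 lists and times, by 0.46 to 0.72, and the median of all probe sets by more, so a call lost or a direction turned is relative to all probe sets and is not a fall of the list. Most probe sets are dimmer than those controls, so the mapping extrapolates for them, and the calls lost or turned carry that limit. It ended the call at 6 h of the cell wall (0.28, mean 2.49 instead of 1.85), jasmonate (0.82, 2.04 instead of 1.5), peroxidase (0.26, 2.28 instead of 1.63) and receptor-like kinase (0.92, 1.51 instead of 0.82) lists, and at 24 h of the cell wall (0.21, 2.89 instead of 2.29), pathogenesis-related (0.15, 3.25 instead of 2.64) and receptor-like kinase (0.88, 1.73 instead of 1.04) lists. It turned downward, relative to all probe sets, the pathogenesis-related (0.35), calcium (5.3e-10), clock (6.9e-05) and cuticle (0.088) lists at 6 h, and the calcium (4e-11), cuticle (0.11), heat shock (8.3e-07) and jasmonate (0.63) lists at 24 h. Lists that were downward without passing then passed, on the same terms, at 6 h for dehydrins (4.9e-14), heat shock (4.9e-14) and phenylpropanoids (7.1e-11), and at 24 h for the clock (3.1e-09), ribosomal (1.5e-08), dehydrin (1.4e-13) and phenylpropanoid (5.6e-08) lists.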

Other observations

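The probe sets of this paragraph lie outside the fixed lists and were picked after their values were seen. They have an annotation only because the study selected them as changed on these same samples. Unchanged probe sets of these families therefore cannot appear, and the counts do not describe whole families. The 8 probe sets whose annotation mentions cycloartenol or cytochrome P450 51, a family that includes sterol demethylases, all rose between 6 h and 24 h. Their rises were 1.18 to 4.48, with limma adjusted p under 0.05. Among them were cycloartenol synthase, a cyclase of sterol and triterpene synthesis, a sterol methyltransferase, and probe sets labelled CYP51H10 and CYP51H11. At 6 h 5 of the 8 were above 0 h with adjusted p under 0.05, and the changes of the others, -0.20 to 0.42, did not pass. At 24 h all 8 were above 0 h, by 0.98 to 5.65. The cycloartenol synthase probe set with the highest rise after 6 h averaged 4.22 at 0 h and 4.64 at 6 h, both within the range of control probe sets without a wheat target (up to 5.36 and 5.03), and 9.12 at 24 h. Its rise of 4.90 ± 0.19 (SE, adjusted p = 1.3e-12), seen in 6 of 6 lines, is a lower bound, as are the rises of the others that started in that range. All 4 annotated probe sets for aquaporin TIP4-1, a water channel family member, rose at 6 h by 3.98 (from background, a lower bound) to 5.31, and between 6 h and 24 h their changes were -3.60 to -2.98.

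The 93 probe sets that moved in opposite directions comprised 29 higher and 64 lower at 6 h, and 21 have a description. Elongation factor Tu fell by 0.65 at 6 h and was 1.88 above 0 h at 24 h. The cold-regulated protein BLT14.1 rose by 1.62 at 6 h and was at -1.44 at 24 h. Of 3 probe sets for PRR1, a regulator of the plant clock and part of the clock list, all rose at 6 h, by 1.38 to 1.96, and at 24 h they were between -0.70 and -0.51, 2 of them with adjusted p under 0.05.

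The array has 64 probe sets whose identifiers begin with RPTR, and 2 of them differed among lines. RPTR-Ta-U43284-1_s_at was at 6.59 ± 0.88 in the line of replicate 4 (SD over 3 times) and at 11.39 to 13.03 in the other lines (adjusted p = 1e-06), the same pattern as RPTR-Ta-K01193-1_at.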
